A study of Drosophila melanogaster with 2 samples.

How the data were processed

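Chromatin immunoprecipitation with an antibody against GFP was done on whole Drosophila melanogaster embryos of 8 to 24 h that express a CG9932-eGFP fusion, per the labels (the age is that of the source name, as the age label holds a number of hours far beyond it), with chromatin broken by sonication to fragments of 200 to 800 bp. The 2 samples are labelled biological replicates 1 and 2 of 1 group. The labels name another experiment as a possible control, and the deposited file descriptions list a control alignment among the inputs of the peak files; neither was analysed here. Reads, alignments and signal tracks were not used here.

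The authors deposited 8 peak lists on dm6, 4 of them ranked lists and 4 sets past a threshold of the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between replicates or between splits of 1 data set. Per the deposited file descriptions, 1 set was derived from each replicate alone, and the conservative and optimal sets from both replicates together. The peak caller, its settings and the aligner are not given in the sources used here. The ranked lists were paired with their sets by containment: each set lies wholly in 1 ranked list. The score of a peak in the deposited lists is the IDR score, a whole number that reached at least 830 in every set, and the deposited -log10 values of the global IDR in the ranked lists put that score at an IDR of 0.0100. The signal of a peak is the value of the authors' caller and was used only to rank, split and describe peaks within a list. Further value columns of the series files, 26 in all, were not used. Summit positions were taken from the deposited lists and are given counted from 1.

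A set kept fewer peaks than its ranked list had past the same score; how these were chosen is not given in the sources used here. The ranked lists are long (124532 peaks for the conservative comparison), with a median spacing of 666 bp between summits. No read depth is given, so the precision of each share comes from the number of peaks, and intervals cover counting error only. With 2 replicates no SD is given, and for some results the values of each replicate's own set stand beside them.

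Genes, transcripts and sequence came from Ensembl release 115 (BDGP6.54), whose coordinates are those of dm6; every peak ended within the length of its arm in this reference. Tests used the conservative set on 2L, 2R, 3L, 3R, 4 and X. A summit was given to the first of these that held it: promoter (500 bp either side of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence. Random positions (1000 draws) kept the arm of each summit and fell on known bases; distances to a TSS used 10 positions per summit. A gene was bound at its promoter when a summit lay within 500 bp of any of its TSS. List tests were two-sided Fisher's exact tests against all other protein-coding genes, and the test on the gene and 2 kb upstream used 10000 random lists matched on gene length in 20 bins. Motif windows reached 100 bp either side of a summit, and flank windows of the same width were centred 500 bp away with no summit within 200 bp of their centre. A motif was called at an adjusted p under 0.05 and an odds ratio of at least 1.5 or at most 0.667. A sequence of 7 bases was called only when higher at summits, at an adjusted p under 0.05, an odds ratio of at least 1.5 and a match in at least 2% of summit windows. Odds ratios and their 95% intervals had 0.5 added to each count, which draws small lists toward 1. Adjusted p-values are Benjamini-Hochberg values over the lists, motifs, features or sequences of each test.

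The 21 lists were Hox, segmentation, neural progenitor, neuronal differentiation, glial, muscle, epidermis, cuticle and trachea, gut and fat body, hemocyte, germline, Notch, Wnt, BMP, EGFR and Hedgehog, Polycomb and trithorax group, cell cycle and DNA replication, cytosolic ribosomal protein, proteasome, oxidative phosphorylation, chemosensory receptor, testis and seminal fluid, and chorion and yolk genes. The last 6 groups were matched by symbol pattern and the others by symbol, of which 10 were changed to the current symbol and 3 were not found. Lists share at most 2 genes with another. Named genes were the nearest genes of the 25 strongest conservative peaks found in both replicates, CG9932, the 3 members of each list with the strongest promoter peak, the first 2 unbound members in alphabetical order of lists called lower or with fewer than 50% bound, and the 5 genes with the most summits.

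Alternatives were promoters of 200 and 1000 bp, the optimal set, the stronger peaks by signal, peak centres, other overlap rules, motif windows of 50 bp, shuffled sequence, matched gene lists and each replicate's own set in place of the conservative one, which leaves the other replicate out. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: the promoter list test on 13945 genes recovered 97.5% of lists planted at 2 times the real rate and 100% of those at 0.3 times, and called 0.833% of unchanged lists. The ribosomal (86 genes) and oxidative phosphorylation (76) lists were planted at 2 times and the chemosensory list (179) at 0.3 times. Recovery of smaller lists was not tested, so these rates do not make a smaller list that was not called a negative result. Simulated promoter shares came back as 38.2% where 38.0% was expected from the planted share, and simulated overlaps as 59.7% where 61.0% was expected from the planted share.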

Results

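The series held 1 group of 2 biological replicates of chromatin immunoprecipitation followed by sequencing (ChIP-seq). The material was whole Drosophila melanogaster embryos aged 8 to 24 h. These flies carried a transgene that makes the product of CG9932 (FBgn0262160) fused to eGFP, and chromatin was recovered with an antibody against GFP. The measurements were peaks, stretches of the dm6 genome where recovered DNA piled up, each with a summit and a signal value from the authors' peak caller. The comparisons ask where the tagged protein was found, and whether both replicates place it at the same sites. The peak lists carry no read counts, so the sequencing depth of each library is unknown and no level is compared between the libraries. No control sample was analysed here.

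The conservative set, which needs a peak to rank alike in both replicates, held 6829 peaks, of which 6790 lay on the chromosome arms 2L, 2R, 3L, 3R, 4 and X. The optimal set held 7328 peaks, and the replicates' own sets held 6036 peaks (replicate 1) and 4549 peaks (replicate 2). The larger replicate set was 1.33 times the smaller, and the optimal set was 1.07 times the conservative one. Of the conservative peaks, 6092 (89.2%) were also in the optimal set. On the arms, 3998 of the 4525 peaks of replicate 2 (88.4%) overlapped a peak of replicate 1 by at least 1 bp, and 4026 of the 6017 peaks of replicate 1 (66.9%) overlapped one of replicate 2. Shuffling the replicate 2 peaks within their arms gave a mean overlap of 2.59% ± 0.233 (SD, 1000 shuffles) and at most 3.43% (two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). Across the 3998 shared peaks the signal values of the replicates were correlated with a Spearman rho of 0.882 (95% interval 0.875 to 0.889). Peaks of 1 experiment are not independent replicates, so no p is given for that value. Its interval, and the p-values over peaks given further on, take peaks as independent and do not measure variation between replicates.

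The strongest conservative peak lay at the promoter of CG14100 (3L, 19590424 to 19590824), with a signal of 7758 and its summit at -94 bp from the transcription start site (TSS; negative is upstream). It ranked first in both replicates' own sets, with a signal of 4387 in replicate 1 and 3401 in replicate 2. The second peak (signal 6087) lay at the promoter of mRpL41, a mitochondrial ribosomal protein gene (2R, 15217546 to 15218021). The third (signal 5967) lay in an intron of CG11050 (2L, 6612472 to 6612924), 1020 bp downstream of its TSS. Ugalt, which encodes a UDP-galactose transporter, followed with a promoter peak of signal 5101 on X (2703693 to 2704086). Of the 25 strongest peaks found in both replicates, 18 had their summit in a promoter, 6 in an intron and 1 in the class of other exons. That summit (X, 12751398) lay 5081 bp downstream of the nearest protein-coding TSS, that of CG4004. It was past the end of CG4004 at 12749785, so in no exon of that gene. The other promoter peaks belonged to CG7601, Shc, eIF6, CG5611, Tcs5, CenG1A, Art3, mRpL23, ph-p, CG8320, CG13390, CG11857, PNPase, GstE13 and Fkbp14. eIF6 encodes a factor of ribosome assembly, and its peak (signal 4429) had its summit over the neighbouring gene ytr. The other intronic peaks were nearest to the TSS of Adf1, HmgZ, CG9663, CG32772 and CG42507. Adf1 encodes a transcription factor, and its peak (2R, 6662864 to 6663277) had a signal of 4119. The peak assigned to CG42507 (3L, 14759273 to 14759736; signal 2926) lay in an intron of Trl, the gene of the GAGA factor. These 25 peaks ranked no lower than 25 in replicate 1 and 29 in replicate 2.

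Promoters, taken as 500 bp either side of a protein-coding TSS, held 3467 of the 6790 summits (51.1%, 95% Wilson interval 49.9 to 52.2). Random positions on the same arms gave 11.5% ± 0.392 (SD, 1000 draws), a 4.44-fold difference. The share was 57.2% in the set of replicate 1 and 57.0% in that of replicate 2. Introns held 31.0% of summits against 39.9% of random positions, and intergenic sequence held 12.1% against 27.8%. Coding exons held 2.84% against 13.9%, and 3' UTRs held 0.928% against 4.52%. These 5 features passed the permutation test (adjusted p = 0.0028 each, two-sided), and the smallest p that 1000 draws can give is 0.002. Each summit counted in 1 feature only, with promoters taken first, so the high promoter share by itself lowers the shares of the others. The lower shares, that of introns among them, thus do not by themselves show that summits avoid these features. A higher promoter share alone would lower all other shares by the same factor, but the ratios to random positions differed. They were 0.775 for introns, 0.434 for intergenic sequence and 0.205 each for coding exons and 3' UTRs. For 5' UTRs and other exons they were 0.853 and 0.924. Introns thus kept more of their random share than intergenic sequence, coding exons and 3' UTRs did. No test was run on summits outside promoters alone. The share in 5' UTRs (0.677% against 0.794%, p = 0.3 by permutation) and in other exons (1.46% against 1.58%, p = 0.458 by permutation) did not pass. In the set of replicate 2 alone 6 features passed, the same 5 and either 5' UTRs or other exons. In that set 5' UTRs held 0.508% and other exons 1.48%. Against the random shares of the conservative set given above, this points to 5' UTRs, with a lower share.

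**Figure D1:**
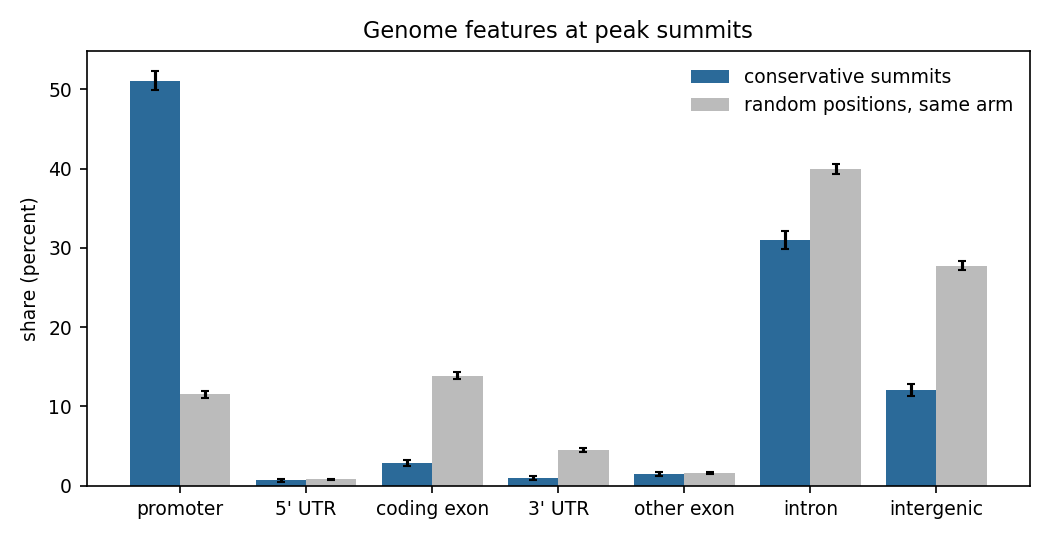
Share of the 6790 conservative summits (blue, bars are 95% Wilson intervals) and of random positions on the same arms (grey, bars are the SD of 1000 draws) in each genome feature, in percent. Promoters took 51.1% of summits and 11.5% of random positions.

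Summits at promoters sat upstream of the TSS. Of the 3467, 2847 lay upstream (82.1%, 95% Wilson interval 80.8 to 83.4). Their median position was -75 bp, with quartiles at -144 and -23 bp. Within 100 bp of a TSS there were 1873 summits, 27.6% of all, against 2.68% of random positions. Over all summits the median distance to a protein-coding TSS was 449.5 bp, against 4226.5 bp for random positions.

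**Figure D2:**
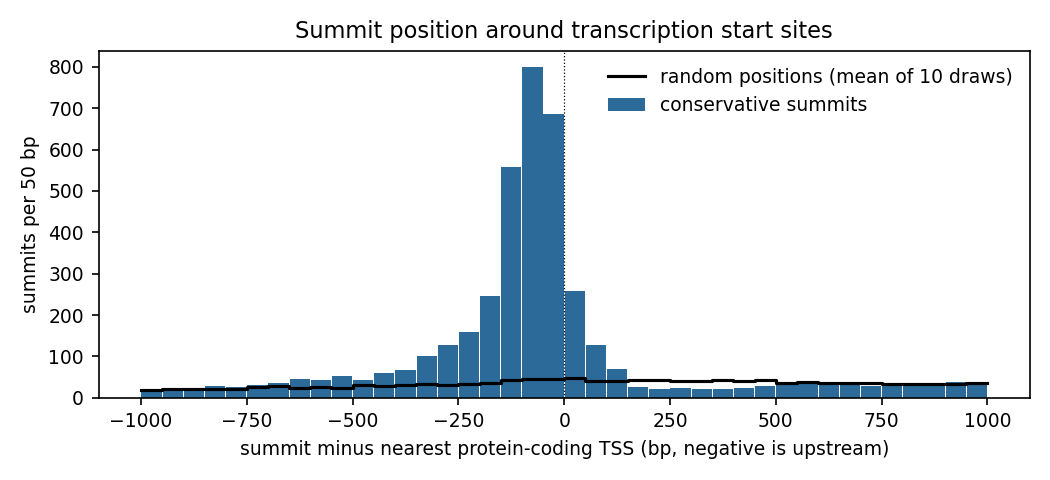
Number of conservative summits per 50 bp by distance from the nearest protein-coding TSS in bp (blue bars, negative is upstream), with the mean of 10 draws of random positions (black line). The summits pile up just upstream of the TSS, around the median of -75 bp.

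Strong peaks lay at promoters more often than weak ones. In the quartile of conservative peaks with the highest signal (median 514), 69.3% of summits were at promoters, and in the next quartiles (medians 218, 126 and 84.6) the shares were 60.4%, 44.5% and 30.1%. The share in introns went from 21.8% in the strongest quartile to 38.2% in the weakest. Promoters were taken first, so the falling promoter share by itself raises that of introns. Weak peaks outside promoters were thus not shown to be more often intronic than strong ones. The odds of a promoter summit in the strongest quartile were 5.22 times those in the weakest (95% interval 4.51 to 6.05, two-sided Fisher's exact test, p = 5.07e-118), and 3.59 times in the set of replicate 1 and 3.58 times in that of replicate 2.

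Peaks were spread over the large arms and nearly missing from chromosome 4. The density was 52.3 peaks per Mb on 2L, 50.3 on 2R, 49.7 on 3L, 49.4 on 3R and 55.4 on X, while chromosome 4 had 1 peak (0.742 per Mb, exact Poisson 95% interval 0.0188 to 4.13) where 68.4 would fall by length. The replicates' own sets had 4 peaks (replicate 1) and 2 peaks (replicate 2) there. Chromosome 4 carries 80 protein-coding genes. The chi-square test against a uniform share gave 79.3 (p = 1.16e-15). The same chi-square test over the 5 large arms alone, an alternative chosen after the data were seen, gave 12.1 (p = 0.0163). The full ranked list, which also keeps peaks that did not pass, had 19 peaks on chromosome 4 where 1216 would fall by length, so the scarcity was already there before the authors' threshold. Whether alignment, peak calling or a filter removed peaks there was not tested, so a missing peak on chromosome 4 does not show that a gene was free of the protein.

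Of the 13945 protein-coding genes on the arms, 4163 (29.9%) had a conservative summit at a promoter. The count was 4203 in replicate 1 and 3328 in replicate 2. Bound genes outnumber the 3467 promoter summits, since 1 summit counts for every gene with a TSS within 500 bp. A peak named with a gene may thus belong to a close neighbour. The list tests take genes as independent, which close neighbours are not. Of 21 gene lists, 3 had more bound promoters than the other genes. Cytosolic ribosomal protein genes stood highest, with 63 of 86 members bound (73.3%, odds ratio 6.43, 95% interval 4.0 to 10.3, adjusted p = 1.11e-15 by Fisher's exact test). The strongest of their promoter peaks were at RpL32 (signal 1645, summit at -138 bp), RpL34b (1319, -103 bp) and RpS27 (1296, -30 bp). Cell cycle and DNA replication genes had 17 of 28 bound (60.7%, odds ratio 3.59, 1.70 to 7.55, adjusted p = 0.00305 by the exact test), led by Dp, a partner of the E2F factors (signal 1169), RnrS, a ribonucleotide reductase subunit (757), and Mcm2, part of the replicative helicase (684). Proteasome genes had 19 of 32 bound (59.4%, odds ratio 3.40, 1.70 to 6.82, adjusted p = 0.00305 by the exact test), with the regulatory subunit genes Rpn6 (signal 1244), Rpn3 (517) and Rpn5 (503) in front. The tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 21 lists. In both replicates' own sets, 56 ribosomal, 13 cell cycle and 16 proteasome genes were bound. In the set of replicate 2 alone the cell cycle list had 46.4% bound and was not called (adjusted p = 0.0509 by the exact test), where the other alternatives gave 0.00204 to 0.0372.

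The chemosensory receptor and the testis and seminal fluid lists had fewer bound promoters than the other genes. Chemosensory receptor genes had 6 of 179 bound (3.35%, odds ratio 0.0866, 95% interval 0.0395 to 0.190, adjusted p = 1.50e-18 by Fisher's exact test), and 4 in the set of replicate 1 and 2 in that of replicate 2, with 1 gene in both; the list was called lower in each set. Their strongest peaks were at Ir60e (signal 367), Gr63a (139) and Or22c (121), while Gr10a and Gr10b had no promoter summit in the conservative set. Testis and seminal fluid genes had 1 of 69 bound (1.45%, odds ratio 0.0511, 0.0101 to 0.258, adjusted p = 6.65e-09 by the same exact test). The sets of replicate 1 and replicate 2 had 2 and 1 bound, and the list was called lower in each. The bound gene was Sfp26Ad (signal 621), and the accessory gland protein genes Acp26Aa and Acp26Ab were unbound. Chorion and yolk genes had 2 of 20 bound (10%) and were not called (adjusted p = 0.123 by the exact test), but were called lower in the set of replicate 1 (5.0%, adjusted p = 0.038 by the exact test). The members bound were Cp190 (signal 1268) and Vm26Ab (104), and Cp110 and Cp15 were unbound. Cp190 encodes an insulator and centrosomal protein and Cp110 a centriolar one, so neither is an eggshell gene. Without both, a choice made after the data were seen, 1 of 18 was bound (adjusted p = 0.0612 by the exact test).

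**Figure D3:**
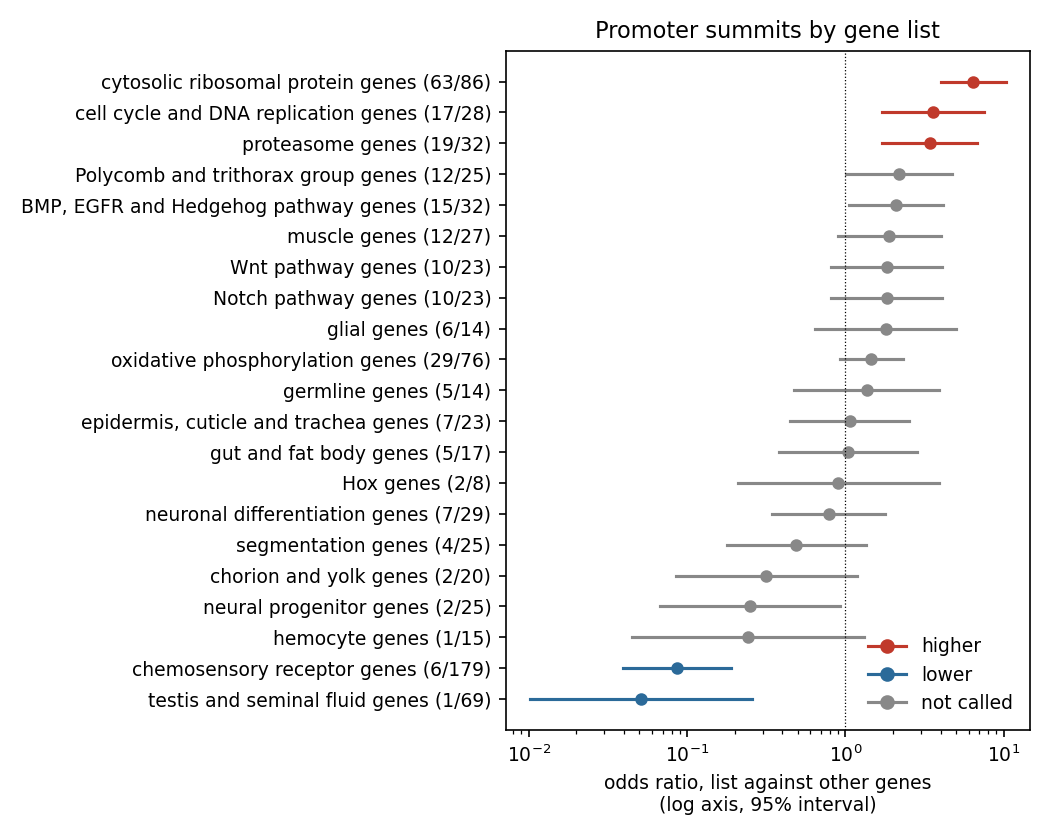
Odds ratio of a promoter summit for the members of each of the 21 gene lists against all other protein-coding genes (points, log axis, with 95% intervals; bound and total members in brackets). The ribosomal, cell cycle and proteasome lists were called higher (red) and the chemosensory and testis lists lower (blue).

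None of the lists of developmental regulators was called at promoters in the conservative set by the exact test. Of the Hox genes, 2 of 8 were bound (25%), Dfd with a signal of 145 and Ubx with 107, each in 1 replicate's own set only, and abd-A and Abd-B were unbound. Within 200 bp of a TSS the Hox share was 0%. Segmentation genes had 4 of 25 bound (16%, adjusted p = 0.263 by the exact test). These included hry (signal 167), sob (102) and en (90.2) but not btd and drm. Neural progenitor genes had 2 of 25 bound (8.0%, odds ratio 0.249, 95% interval 0.0677 to 0.919, adjusted p = 0.0523 by the exact test). They were brat (316), a regulator of neuroblast differentiation, and grh (128), and the proneural genes ac and amos were unbound. Hemocyte genes had 1 of 15 bound (6.67%, adjusted p = 0.123 by the exact test), ush (signal 249), and Col4a1 and crq were unbound. Against random lists matched on the number of TSS and on gene length, both lists were called lower (adjusted p = 0.0084 and 0.0308 by permutation). Matched on the DNA replication-related element, Motif 1 and the number of TSS, a choice made after the data were seen, they were also called lower (adjusted p = 0.0399 each by permutation). Their other alternatives gave 0.0176 to 0.198 for the neural progenitor list and 0.123 to 0.509 for the hemocyte list. The sets of replicate 1 and replicate 2 had 3 and 2 segmentation, 3 and 1 neural progenitor, and 2 and 1 hemocyte genes bound.

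The lists of differentiated tissues held strong peaks at single genes without passing the test. Neuronal differentiation genes had 7 of 29 bound (24.1%), with elav, the pan-neuronal RNA-binding protein gene, at a signal of 1764, Nrx-1 at 366 and Fas2 at 165, and with brp and cac unbound. Glial genes had 6 of 14 bound, among them moody (signal 2166), a receptor gene of the blood-brain barrier, Nrg (205) and ana (152) but not Eaat1 and gcm. Muscle genes had 12 of 27 bound, with Msp300 (1314), sls (718) and mbc (592) in front and bap and bt unbound. Epidermis, cuticle and trachea genes had 7 of 23 bound, such as trh (214), crb (209) and Ddc (189), and bnl and btl had none. Gut and fat body genes had 5 of 17 bound, led by bowl (1021), Adh (333) and Hnf4 (294), without byn and cad. Germline genes had 5 of 14 bound, with nanos (890), bgcn (368) and vas (274) but neither AGO3 nor aub. Across these 6 lists the adjusted p ran from 0.241 to 1 by Fisher's exact test. Several shares were lower in the set of replicate 2 than in that of replicate 1: 21.4% against 50% for glial genes (odds ratios 0.971 and 2.32), 25.9% against 37.0% for muscle (1.17 and 1.39), 13.8% against 27.6% for neuronal differentiation (0.562 and 0.916), and 17.4% against 26.1% for epidermis, cuticle and trachea genes (0.736 and 0.861). Many named summits lay over 200 bp from the TSS, such as nanos (-371 bp), Msp300 (-355 bp) and elav (-254 bp). Others lay nearer, such as moody (-163 bp) and Nrg (-57 bp). Within 200 bp of a TSS the shares were 5.88% for gut and fat body, 14.3% for germline and 17.2% for neuronal differentiation genes. They were 21.7% for epidermis, cuticle and trachea, 22.2% for muscle and 28.6% for glial genes. None was called there by the exact test.

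Signalling, chromatin and respiratory chain lists had higher shares of bound promoters that did not pass. Random lists matched on the number of TSS and gene length had 39.5% bound for Wnt and 38.0% for BMP, EGFR and Hedgehog genes. The matched shares were 38.1% for Polycomb and trithorax, 30.2% for Notch and 28.1% for oxidative phosphorylation genes. None of these lists was called against the matched ones (adjusted p from 0.167 to 0.98 by permutation). Notch pathway genes had 10 of 23 bound (43.5%, adjusted p = 0.258 by the exact test), including gro (signal 977), numb (965) and Su(H) (415), and Delta and E(spl)m4-BFM were unbound. Wnt pathway genes also had 10 of 23 bound, with sgg (980), nkd (683) and Apc2 (298) but not arr and fz3 in the conservative set. In the sets of replicate 1 and replicate 2 the Wnt list had 30.4% and 21.7% bound, with odds ratios of 1.05 and 0.948, so its higher share was not found there. BMP, EGFR and Hedgehog pathway genes had 15 of 32 bound (46.9%, adjusted p = 0.123 by the exact test), led by spi (878), dlp (726) and aos (218), with ci and cos unbound. Polycomb and trithorax group genes had 12 of 25 bound (48%, adjusted p = 0.161 by the exact test). They held ph-p (signal 3163; X, gene from 2126210 to 2138371) and E(z) (1148), which encode subunits of the Polycomb complexes, and brm (2559), the ATPase gene of a chromatin remodeller, while ash1 and Caf1-55 were bound in the set of replicate 1 only. In the optimal set both of the last lists were called higher, at 56.3% and 60% (adjusted p = 0.0117 for each by the exact test). The Polycomb and trithorax list was also called in the set of replicate 1 (64% bound, adjusted p = 0.00299) and within 200 bp of a TSS (adjusted p = 0.0249), both by the exact test, and its other alternatives gave 0.0925 to 0.525. Oxidative phosphorylation genes had 29 of 76 bound (38.2%, adjusted p = 0.241 by the exact test), such as ND-ASHI (1209), ND-MWFE (840) and ND-24 (720), with ATPsynbeta and ATPsynbetaL unbound. ATPsynbeta, bt and ci lie on chromosome 4, where 1 conservative peak was found and a missing peak is no evidence.

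Counting summits anywhere in the gene or up to 2 kb upstream, 5582 protein-coding genes (40.0%) were bound, and 7 of the 21 lists stood apart from random lists matched on gene length. Ribosomal protein genes had 81.4% bound against 30.4% in matched lists, and chemosensory receptor genes had 10.1% against 35.7% and testis and seminal fluid genes 5.8% against 21.9% (adjusted p = 0.0014 each, permutation test with 10000 lists, from the smallest raw p they can give, 0.0002). In the sets of replicate 1 and replicate 2 the chemosensory share was 5.59% and 3.91% and the testis and seminal fluid share 7.25% and 2.90%, called lower in each. Proteasome genes had 62.5% against 33.0% (adjusted p = 0.0091 by permutation), oxidative phosphorylation genes 48.7% against 29.9% (adjusted p = 0.00315 by permutation) and cell cycle and DNA replication genes 67.9% against 43.9% (adjusted p = 0.0462 by permutation). Without the match on length the oxidative phosphorylation list was not called (adjusted p = 0.189 by Fisher's exact test, 48.7% against 40.0% of other genes). Neural progenitor genes had fewer than matched lists, 16.0% against 47.7% (adjusted p = 0.00672 by permutation). The cell cycle call was lost in the optimal set (adjusted p = 0.0682) and in the sets of replicate 2 (0.16) and replicate 1 (0.0744) alone, all by permutation. Lists called by the same permutation test in a replicate's own set alone were segmentation genes in both (20% bound, adjusted p = 0.0283 in replicate 1; 12%, 0.0168 in replicate 2), neuronal differentiation genes in replicate 2 (31.0%, 0.0451), and in replicate 1 Polycomb and trithorax (84%, 0.0028), hemocyte (20%, 0.0308) and chorion and yolk genes (5.0%, 0.0496). Of these the Polycomb and trithorax list was higher than matched lists and the others lower. The genes with the most summits were kirre (19), CG1677 (16), bun (16), CHES-1-like (15) and sbb (15). kirre, a cell adhesion gene of myoblast fusion on X (2740384 to 3134532), had no promoter summit, and CHES-1-like (X, 7682338 to 7709385), the shortest of the 5 at 27048 bp, held 51.6 summits per 100 kb of gene and upstream sequence.

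Windows of 100 bp either side of the summits differed in sequence from flank windows 500 bp away. The DNA replication-related element TATCGATA, the site of DREF, was in 5.43% of 6790 summit windows and in 0.529% of 12862 flank windows (odds ratio 10.7, 95% interval 8.29 to 13.9, adjusted p = 9.25e-104 by Fisher's exact test); the odds ratio was 13.1 in the set of replicate 1 and 10.1 in that of replicate 2. The core promoter element Motif 1 (GGTCACAC, bound by M1BP) was in 3.17% against 0.521% (odds ratio 6.21, 4.72 to 8.18). The CTCF core AGRTGGCG was in 2.90% against 1.34% (odds ratio 2.20, 1.79 to 2.71). TATA box and Mef2 site matches were more frequent at summits by odds ratios of 1.57 and 1.56, and ETS core (0.657) and CA repeat (0.587) matches were less frequent. None of these 4 was called the same way against shuffled summit sequence (TATA 1.34, Mef2 1.35, ETS 0.863; the CA repeat turned to 4.43) or at summits away from any TSS (1.16, 1.0, 0.782 and 0.704), and TATA was not called in windows of 50 bp either side (1.48). The other 16 of the 23 motifs, GAGA repeats, Zelda sites and E-boxes among them, did not pass the two-sided Fisher's exact test with the added bound on the odds ratio. Some of these passed in alternatives. GAGA repeats were lower in windows of 50 bp either side (0.617) and away from any TSS (0.663) but higher against shuffled sequence (4.84), where CAGCTG (2.65) and A runs (1.73) were also higher. Zelda sites were lower in the sets of replicate 1 (0.601) and replicate 2 (0.654), and homeodomain cores were higher in the latter (1.52). At the 3178 summits farther than 500 bp from any TSS, the odds ratio was 2.93 for CTCF, 0.982 for the DNA replication-related element and 1.2 for Motif 1, and CTCF was the only motif called higher there. Mean GC content was 40.0% in summit and 43.2% in flank windows.

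**Figure D4:**
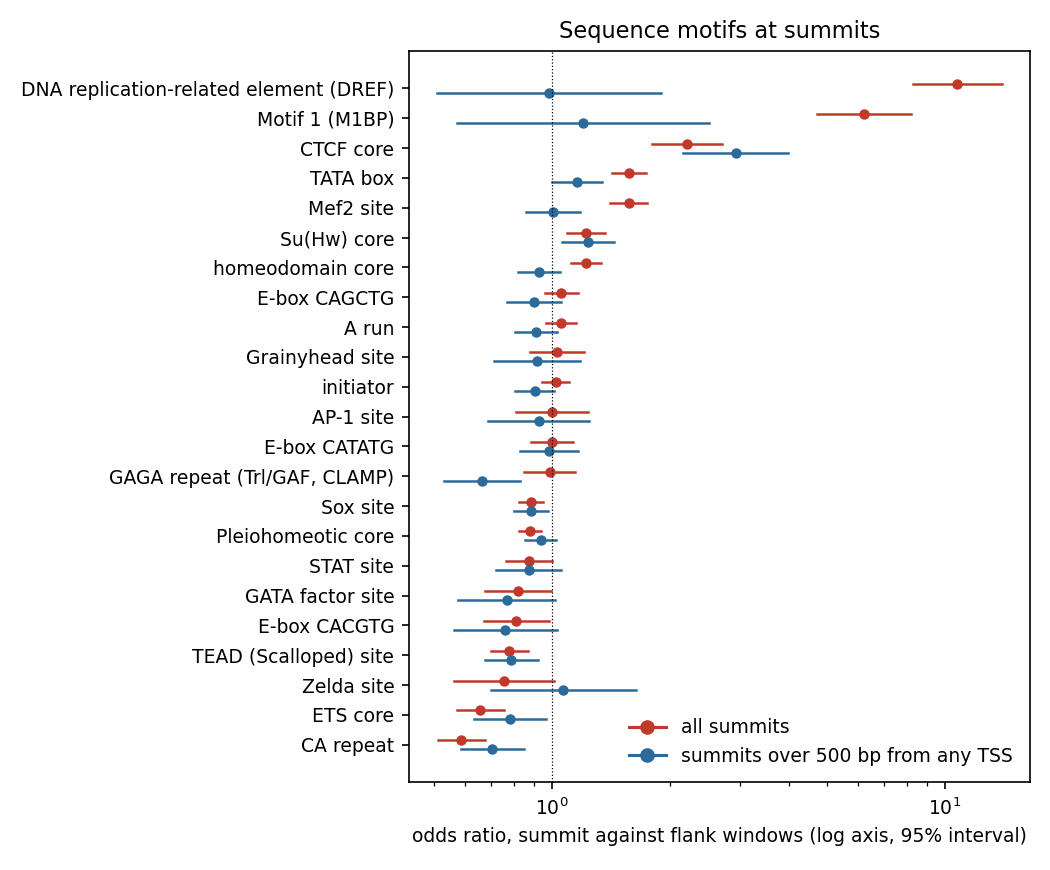
Odds ratio of a match in summit against flank windows for each of the 23 motifs (points, log axis, with 95% intervals), for all 6790 summits (red) and for the 3178 farther than 500 bp from any TSS (blue). For the DNA replication-related element the values are 10.7 and 0.982.

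Of 8192 sequences of 7 bases, 320 were called higher in summit than in flank windows by the same exact test, each in at least 2% of summit windows. Sequences lower at summits were not called. The highest odds ratio was that of CTATCGA, in 8.14% of summit windows against 1.40% of flank windows (6.23, 95% interval 5.26 to 7.40), and ATCGATA was in 11.2% against 2.44% (5.05, 4.41 to 5.78). Of the 10 highest, 6 held CGATA or its reverse complement, the core of the DNA replication-related element. The others were AGCCCTG, AGGGCTG, ACAGTGG (8.11% against 2.54%) and CAGTGTA (5.27% against 1.62%). At summits away from any TSS 124 were called, 79 of them also called over all summits, and the highest was CACAGTG (8.90% against 2.40%, odds ratio 3.97, 3.24 to 4.87). Of the 10 highest over all summits, 2 were called there, ACAGTGG and CAGTGTA.

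The tagged gene CG9932 itself (2L, 13021868 to 13060140, minus strand) held several peaks, counted because the flies carry extra DNA of this gene. The conservative set had 5 summits in the gene, where 2.00 would fall by the density of the arm, and 16 within 50 kb, where 7.23 would fall. Replicate 1 had 6 in the gene and 15 within 50 kb, and replicate 2 had 6 and 13. At the gene's own promoter a peak (13060105 to 13060474) had its summit at -150 bp from the TSS and a signal of 304, rank 1744 of the conservative peaks. Of the 5 summits in the gene, 2 lay in introns (signals 201 and 125) and 3 in coding exons (125, 109 and 107). The strongest peak of the region lay in intergenic sequence (13083672 to 13083996; signal 1299, rank 145), followed by the promoter of Ube4B (13019092 to 13019362; signal 1084, rank 228).

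**Figure D5:**
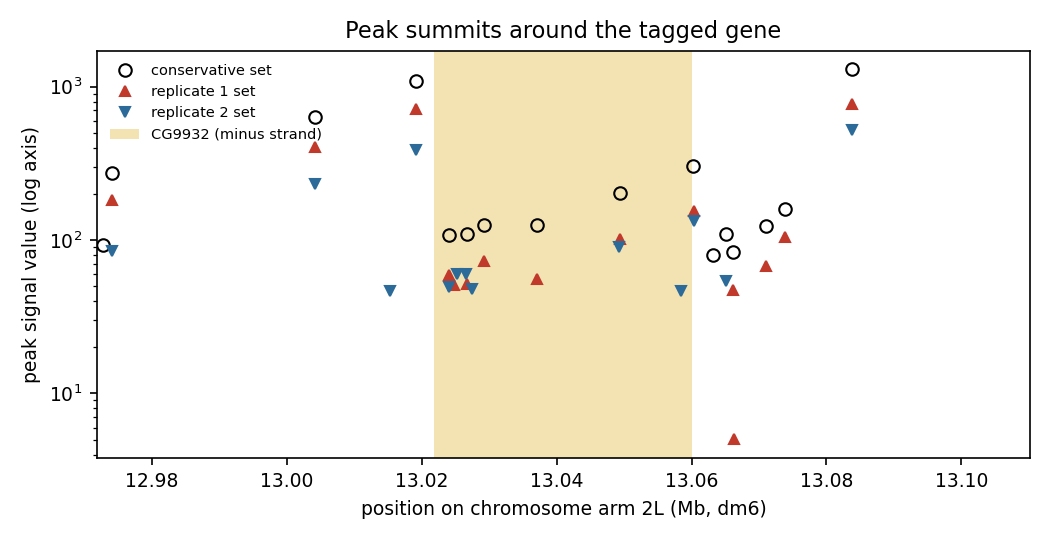
Signal value (log axis) of each peak by position of its summit on 2L (Mb, dm6) around CG9932 (shaded) for the conservative set (circles) and the sets of replicate 1 (red triangles) and replicate 2 (blue triangles). The 5 conservative summits in the gene have signals of 107 to 201, and signals are not compared between sets.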

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

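The results in this part count peaks outside the main comparisons; all were looked at only after the peak lists had been seen, and no test was run on them. Outside the 6 chromosome arms the conservative set held 39 peaks, above the 3 that a count of 0 allows. Of these, 38 lay on 32 unplaced scaffolds of X and 1 on the Y chromosome, with a median signal of 101.

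The ranked list held 236 peaks that reached the score of the conservative set but were not kept in it, 3.34% of those that reached it. By place, 111 of the 1696 peaks past the score on 3R, 44 of 1273 on 2L, 12 of 1285 on 2R, 11 of 1315 on X, 9 of 1407 on 3L, 3 of 4 on chromosome 4 and 46 of 85 on other scaffolds were not kept. Their median signal was 158, against 160 for the kept peaks, and 86 of the 190 on the arms (45.3%) were at promoters. A pair of them were stronger than the weakest of the 25 named peaks. They lay in an intron of ush (2L, 480879 to 481291; signal 4958), at -1404 bp from the TSS of cbt, and in an intron of Lk6 (3R, 11760856 to 11761233; signal 3321), at -968 bp from its TSS. No explanation was tested for either result.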

How the results depend on the processing

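Most alternatives were fixed before the data were examined; those chosen only after the result was seen were chromosome density without chromosome 4, genome features and the tagged gene in the other peak sets, and the chorion list without Cp190 and Cp110. Of 46 alternatives to the results that answer a comparison, 42 gave a value in the same direction and on the same side of the threshold, or a count within 1.5 times, which does not say which members were called. Peak centres in place of summits, counted among them, were a weak check. Of the conservative peaks, 64.7% shared a width of 370 bp, which keeps centre and summit close. The promoter fold ranged from 2.98 (1000 bp) to 7.90 (200 bp), and the replicate overlap from 72.8% to 96.0%. Pairing peaks by summits within 100 bp moved the rank correlation of the shared peaks from 0.882 to 0.912. Without the match on gene length, 11 lists in place of 7 were called for summits in the gene or 2 kb upstream, 6 of them in both, and the oxidative phosphorylation list was no longer called. With summits away from any TSS alone, 2 motifs in place of 7 were called (1 in both) and 124 sequences of 7 bases in place of 320. This alternative tests 3178 of 6790 summits, and it turned the odds ratio of the DNA replication-related element from 10.7 to 0.982. Against shuffled summit sequence 7 motifs were called as well, but 3 of them in both, and the odds ratio of the CA repeat turned from 0.587 to 4.43; the cause was not tested. Of 110 alternatives to single lists and motifs that were called, 94 gave the same call, 14 lost it, and 2, those of the 2 motifs above, passed to the other side of an odds ratio of 1, where the CA repeat was called and the DNA replication-related element was not. Of 281 alternatives to those not called, 254 gave no call and 27 gave one. Leaving out a replicate gave chi-square values of 58.6 to 76.7 for the arms and 8 to 10 called lists in the gene or 2 kb upstream, and the optimal set gave 6. No paired analysis was possible because the samples form 1 group. Unknown read depth limits any statement on sites without a peak.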

Other observations

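The tests in this part were chosen only after the result was seen, except those on the number of peaks at the tagged gene, on the 5 called lists together from peaks that did not pass and on the share of the smaller replicate set. Promoter and distant summits differed in sequence. The DNA replication-related element was in 10.3% of 3467 promoter windows and 0.409% of 3178 windows farther than 500 bp from any TSS (odds ratio 26.9, adjusted p = 5.13e-84, two-sided Fisher's exact test), and Motif 1 was in 5.83% against 0.346% (odds ratio 17.1). The E-box CAGCTG was in 13.2% against 7.80%. Su(Hw) core matches were less frequent at promoters (6.63% against 9.0%, adjusted p = 0.000977 by the exact test), and CTCF core matches (2.51% against 3.24%, adjusted p = 0.123 by the exact test) did not pass. Protein-coding genes with the DNA replication-related element at a promoter were bound in 50.7% of cases (917 of 1810), against 26.7% of those without it (Fisher's exact p = 1.26e-88), and genes with Motif 1 in 47.6% (775 of 1629) against 27.5% (Fisher's exact p = 5.72e-58). Genes were not matched on the number of TSS in these tests, and more TSS give more sequence that can hold a motif and a summit.

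Other gene classes had lower shares of bound promoters than the 29.9% of protein-coding genes, with no test run between classes. Counting genes whose TSS lay away from any protein-coding promoter, the shares were 111 of 2320 ncRNA genes (4.78%), 7 of 211 tRNA genes (3.32%), 6 of 184 snoRNA genes (3.26%) and 4 of 27 snRNA genes (14.8%). No summit lay at 99 rRNA genes or at 188 pseudogenes. Counting error alone allows shares of up to 3.03% and 1.60%, and whether peaks could be called at such sequence was not measured. Annotated transposable elements held 18 summits (0.265%) against 5.77% ± 0.289 of random positions (permutation p = 0.002, the smallest that 1000 draws can give). Whether peaks could be called in transposable elements was not measured either, so this does not show that the protein was absent there. The X chromosome had 1.10 times the peak density of the autosomes 2L to 3R (95% interval 1.04 to 1.17, two-sided exact binomial p = 0.00207), and 1.15 times in replicate 1 and 1.12 times in replicate 2. In the optimal set the ratio was 1.06 (95% interval 1.00 to 1.13, exact binomial p = 0.0481), with the interval barely above an equal density.

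Replicate 1 had 1991 peaks that replicate 2 did not share, with a median signal of 67.5 against 158 for its shared peaks, and replicate 2 had 527 of its own, with 56.1 against 113. Fewer of them were at promoters, 49.6% against 61.0% in replicate 1 (Fisher's exact p = 3.51e-17) and 28.3% against 60.8% in replicate 2 (Fisher's exact p = 1.20e-45). Of the peaks of replicate 1 alone, 89.6% overlapped a peak of the full ranked list of replicate 2, against 46.4% after shuffling, and of those of replicate 2 alone 87.1% overlapped the ranked list of replicate 1, against 41.0%. A candidate explanation is that the library of replicate 1 reached further down 1 shared ranking, which would put at least 90% of the smaller set in the larger. The share was 88.4%, between that bound and the 50% that would speak against it, so this stays open, and no biological explanation was tested since the samples form 1 group.

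The tagged gene held 10 conservative peaks in a window of 58273 bp (the gene and 10 kb either side), where random windows of its arm have a median of 2 (95th percentile). Extra copies of transgene DNA could raise the signal over the whole fragment. The number of ranked peaks, 59 against a median of 54, stood at percentile 58.4 of 1000 windows, between the bounds of 50 and 95 set for it, so it decides nothing. The ranked peaks that did not pass had a median signal of 37.7 in this window against 27.9, percentile 97.4, as extra DNA would give. Binding of the protein at its own gene stays open beside it, since DNA without immunoprecipitation was not analysed here.

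The 5 called promoter lists could follow from active promoters that gather peaks whatever the antibody. Ranked peaks that did not pass gave 0 of the 5 odds ratios inside the interval of the conservative set (0 of 2 lists called lower, 0 of 3 called higher), a count set to speak against this explanation; among unbound genes alone the odds ratios were 0.302 to 1.06, with an interval apart from that of the conservative set for 4 of the 5 lists, all but the cell cycle list. That reading was wrong for both directions and the explanation stays open, since such peaks do not mark promoters rich in peaks: 10.4% of them lay at promoters against 11.5% of random positions. They were found at 38.0% of bound and 61.0% of unbound promoters (Fisher's exact p = 2.65e-138). Ranked summits lie apart (median 666 bp, 1.15% of gaps under 200 bp), which leaves less room for such peaks at a bound promoter. A difference in this direction could follow from that spacing alone, so it is no evidence on active promoters. Against random lists matched on the DNA replication-related element, Motif 1 and the number of TSS, 4 of the 5 lists were called the same way, which speaks against exact matches of these motifs as the whole cause. The neural progenitor and hemocyte lists were called lower as well (adjusted p = 0.0399 each by permutation). Variant sites were not matched, and ATCGATA alone was in 11.2% of summit windows against 5.43% for the full element. Gene length was not matched here, and a part played by variant sites stays open for every list. The proteasome list was not called (adjusted p = 0.066 by permutation; 59.4% bound against 39.0% in matched lists, from 28.2% matched on TSS and length), and for it a part played by the motifs stays open.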
